A study of Mus musculus with 4 samples.

How the data were processed

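RNA from lineage-negative, cKit-positive, Sca1-positive foetal liver cells of Hes1 GFP/WT mouse embryos at E13.5 was hybridized to Affymetrix arrays, 3 labelled HES1-GFP negative and 1 labelled HES1-GFP positive. Per the labels' protocols, total RNA was taken with a column kit, 5 ng was amplified with a Nugen Ovation system, and the resulting cDNA was labelled with biotin. Amplification from so little RNA can add noise, to dim genes among others, and its size was not measured here. Per the submitters' processing notes the values were made with RMA, which corrects background, equalizes the distributions of the arrays and summarizes the probes of each probe set. The version and the software are not given in the sources used here. The deposited values are probe set intensities on a linear scale, from 4.27 to 27451.5, with no negative or missing value, although RMA usually gives log2 values. That the scale is linear and not centred per gene follows from the values themselves. The scanner files were not used here, so the background correction and the normalization could not be varied from the start, and no detection calls were at hand. The 4 columns have nearly equal quantiles, with medians of 75.3, 76.1 and 74.8 for negative replicates 1, 2 and 3 and 75.0 for the array labelled positive. A difference in total RNA per cell cannot be seen in values equalized in this way.

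The intensities were turned into log2 values with no pseudocount, a step not foreseen in the design, which had assumed log2 RMA values. Of 45101 probe sets, 64 control probe sets were set aside, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 carried none. Only probe sets with 1 symbol were named, and 34741 of them matched the reference gene table (GRCm38.p6) by gene ID. No coordinates are given, since the arrays name no genome build. For each of the 18193 genes the probe set with the highest mean over the 4 arrays was used, and 9010 genes had more than 1. No filter on level was applied.

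The fixed design compared positive with negative in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, without trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The spread came from the 3 negative arrays alone (2 residual degrees of freedom, 1.92 prior degrees of freedom from all genes), and the lone positive array was assumed to vary like them. As a description without a variance model, genes were counted whose positive value lay at least 1 log2 unit outside the range of the negative arrays, and each negative array was counted against the other 3 in the same way. Gene lists fixed before the data were examined (24 lists of blood lineages, other liver cell types, Notch signalling and general cell functions, and 1 sex check list given by value) were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. With an estimated correlation camera tests each list on the residual degrees of freedom, 2 here and 1 without a negative replicate. Hardly any list can then pass, whatever its correlation. fry asks whether a list's genes move, on balance, 1 way, without comparing them with other genes. It too rests on the residual degrees of freedom, so a list can hardly pass it here. Of the genes in the 24 lists, 43 entries were not measured by a probe set of their own. Each list's median was also ranked among 10000 random lists matched on mean level.

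The genes named in the text were set by a rule fixed at the same time as the lists. It takes Hes1, then the 12 genes in each direction with the largest log2 difference among those past the threshold and outside the negative range, filled up with the genes of the largest absolute moderated t where fewer passed, and up to 4 members per list with the largest absolute moderated t. Unnamed clones and predicted genes were left out. Since no gene passed, all named genes are given as values.

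The fit was tested on 10 simulated data sets of the 18193 genes with the real means and fitted spreads and 200 changed genes each. For positive against negative with 1 against 3 arrays, it called 0.296% of genes changed by 1 log2 unit, 19.3% of those changed by 2 and 90.1% of those changed by 4, with 4.4 false calls per data set on average. A list shifted by 1 log2 unit was called by camera in 9 of 10 data sets. The spreads drawn were those after limma's moderation, which vary less between genes than the unmoderated ones. The shares called may therefore be too high for the real data. These simulations held no structure shared between arrays, and each gene was drawn independently of the others. The 9 of 10 therefore does not describe camera on lists whose genes vary together.

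The alternatives were cyclic loess normalization of the columns, a filter keeping probe sets above the median level, eBayes with trend and robust settings, averaging all probe sets of a gene, limma's treat with a minimum log2 difference of 0.5, a fit of all probe sets, an estimated correlation and fry for the lists, and leaving out each negative replicate in turn. A comparison with negative replicate 3 alone, and an estimated correlation within the refits with a filter, with averaged probe sets or without a negative replicate, were added after seeing the data.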

Results

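Gene expression was measured by microarray in haematopoietic progenitors sorted from mouse foetal liver at the E13.5 stage. The sorted cells were negative for lineage markers and positive for cKit and Sca1 (LSK cells), the fraction of the foetal liver that holds haematopoietic stem cells and multipotent progenitors. The embryos carried a GFP reporter at 1 allele of Hes1, a transcriptional repressor switched on by Notch signalling, and the cells were divided by GFP into HES1-GFP negative (3 arrays) and HES1-GFP positive (1 array). The comparison the labels set up is GFP positive against GFP negative LSK cells at 1 stage. The 4 arrays had median probe set intensities of 74.8 to 76.1 on the linear scale, so that their overall brightness was nearly equal. The labels do not say whether the 3 negative samples came from separate litters or sorts, so their spread may be partly technical. The single positive array gives no spread of its own, and every p-value below assumes that it varies like the negative arrays. The number of arrays limits the precision of every value, and an exact permutation of the labels over 4 arrays cannot give a one-sided p below 0.25.

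Hes1, the gene that carries the reporter, did not follow the labels. Its log2 intensity was 8.78 and 9.07 in HES1-GFP negative replicates 1 and 2, 6.70 in negative replicate 3, and 6.57 in the array labelled HES1-GFP positive, the lowest of the 4. The array labelled positive therefore lay 1.62 log2 units below the mean of the negative arrays, 8.18 ± 1.30 (SD, n = 3), with a standard error of 1.08 and a limma adjusted p of 1.00. Because the reporter gene goes against its label, the groups are called by their labels throughout, and every direction below is that of the array labelled positive against the arrays labelled negative. Without negative replicate 3 the difference in Hes1 was -2.36 log2 units with an adjusted p of 0.305.

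**Figure D1:**
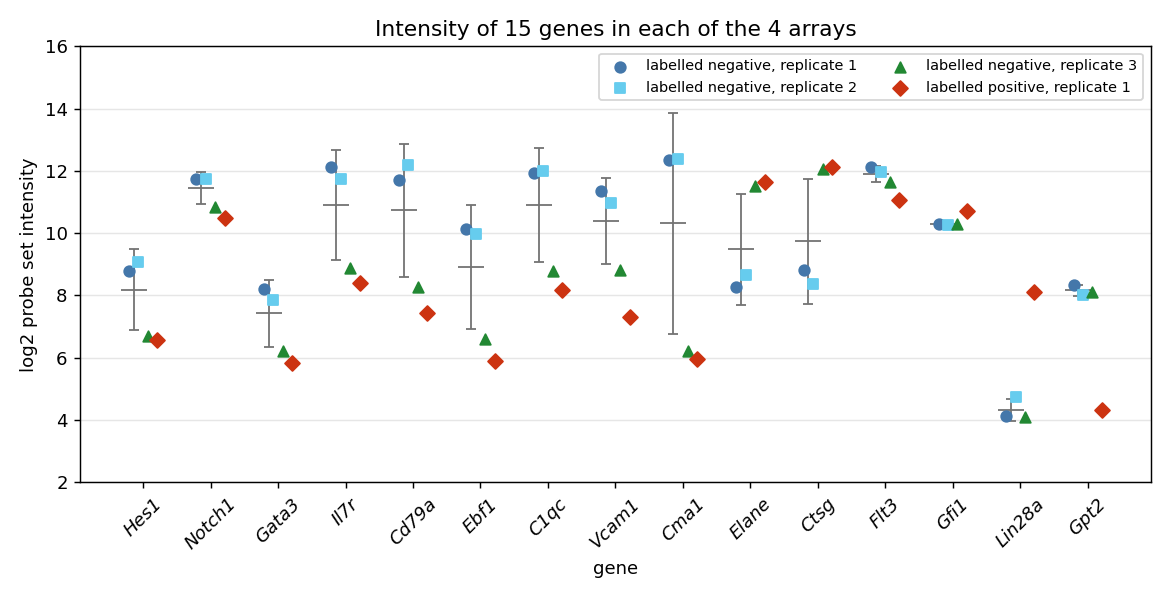
Log2 probe set intensity (y axis) of 15 genes (x axis) in each of the 4 arrays, 1 marker per array; the grey dash and bars give the mean and SD of the 3 arrays labelled HES1-GFP negative. For Hes1, Notch1, Gata3, Il7r, Cd79a, Ebf1, C1qc, Vcam1 and Cma1 the array labelled positive and negative replicate 3 sit below negative replicates 1 and 2, for Elane and Ctsg they sit above them, and for Lin28a and Gpt2 the array labelled positive stands apart from all 3 negative arrays.

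The 4 arrays were compared with each other over all 18193 genes. The array labelled positive and negative replicate 3 were the closest pair, with a Pearson correlation across genes of 0.980 and 1170 genes at least 1 log2 unit apart. Negative replicates 1 and 2 had a correlation of 0.973 and 1600 such genes. The other 4 pairs had correlations of 0.962 to 0.964 and 1950 to 2072 such genes. Genes are not independent replicates, and these correlations describe the arrays only. The first principal component, 51.7% of the variance, placed negative replicates 1 and 2 at -38.0 and -40.1 and negative replicate 3 and the array labelled positive at 39.5 and 38.7.

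No single gene passed the test between the labelled groups. limma called 0 genes higher and 0 genes lower at an adjusted p under 0.05 among 18193 genes, and the lowest adjusted p was 0.820. At an unadjusted p under 0.05, limma gave 734 genes, 482 higher and 252 lower, where chance gives about 909.7 of independent genes. The same count was 1138, 1300 and 800 for negative replicates 1, 2 and 3, each taken alone against the other 3 arrays. limma's treat test against a minimum log2 difference of 0.5 called 0 genes, with 273 at an unadjusted p under 0.05. limma with trend and robust settings called 0 genes (622 unadjusted), and limma over all 45037 probe sets called 0 (2032 unadjusted). The distance of negative replicate 3 from replicates 1 and 2 enters the spread that limma uses. The unadjusted counts therefore do not show that the labelled groups differ less than by chance. The array labelled positive lay outside the range of the 3 negative arrays in 46.6% of genes, where chance gives 50%. It lay at least 1 log2 unit above that range in 153 genes and below it in 103, a total of 256. The balance turned with only probe sets above the median level, to 68 above and 88 below. That filter uses the mean over all 4 arrays, 3 of them negative. It therefore drops genes high only in the array labelled positive more readily than genes low only there. With averaged probe sets the counts were 119 above and 49 below. The same count was 377 for negative replicate 1, 431 for negative replicate 2 and 298 for negative replicate 3, each set against the other 3 arrays. Against 2 negative arrays the count for the array labelled positive was 419 without replicate 1, 417 without replicate 2 and 916 without replicate 3, and a range of fewer arrays is narrower by construction. Against the full set of other arrays, the array labelled positive stood apart from the rest less than any negative array did.

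The genes furthest from the 3 negative arrays for their spread are given as values, since none passed the test. Lin28a, an RNA-binding protein that blocks maturation of the let-7 microRNAs, had a log2 intensity of 8.11 in the array labelled positive and 4.32 ± 0.36 (SD, n = 3) in the negative arrays. Its second probe set differed in the same direction, by 1.36 log2 units. There the array labelled positive was at 5.11 against 3.27, 3.44 and 4.54 in negative replicates 1, 2 and 3, with replicate 3 the closest. Pdcd1lg2, a ligand of the inhibitory receptor PD-1, was at 8.22 against 5.22 ± 0.32 (SD, n = 3). Tnfrsf25, a death-domain receptor of the TNF receptor family, was at 8.63 against 5.95 ± 0.25 (SD, n = 3). Polr3gl, a subunit of RNA polymerase III, was at 9.46 against 7.34 ± 0.10 (SD, n = 3), and Lgals2, a galectin, at 7.16 against 4.26 ± 0.11 (SD, n = 3). The other genes on the higher side were Bpifc, Plcxd2, Ppil6, Klra5, Amdhd1, Syt3 and Hsd11b2, with differences of 1.63 log2 units for Hsd11b2 to 3.63 for Bpifc. Of the 12 genes on the higher side, 9 (all but Polr3gl, Tnfrsf25 and Syt3) had no probe set with a mean above the median level of all probe sets, and no detection calls were at hand for them. Amdhd1 differed by 2.10 log2 units. The probe set used for a gene was that with the highest mean over all 4 arrays, the array labelled positive included. For Lgals2, Plcxd2 and Amdhd1 the other probe set had the higher mean over the negative arrays. Those other probe sets differed by 1.09, 0.88 and -0.43 log2 units. Klra5 belongs to a family of near-identical receptor genes whose probes may share signal.

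On the lower side, Gpt2, a mitochondrial alanine aminotransferase, was at 4.33 in the array labelled positive against 8.16 ± 0.16 (SD, n = 3) in the negative arrays. The other 3 probe sets of Gpt2 differed by -0.78, -0.10 and -0.11 log2 units. Ccr7, a chemokine receptor of lymphoid cells, was at 5.52 against 8.76 ± 0.54 (SD, n = 3). Slco2b1, an organic anion transporter, was at 5.23 against 7.65 ± 0.16 (SD, n = 3), and Pvt1, a long non-coding RNA next to Myc, at 5.29 against 7.43 ± 0.18 (SD, n = 3). The remaining genes were Myl10, Insyn2b, Nr2c1, Farp1, Csrnp1, Glis2, Trim26 and Fhit, with differences from -1.32 log2 units for Glis2 to -2.62 for Insyn2b. The limma adjusted p of the 24 genes was 0.820 or higher. Of the 12 that had several probe sets, 6 (Amdhd1, Slco2b1, Pvt1, Nr2c1, Glis2 and Trim26) had probe sets that differed in opposite directions. Averaging the probe sets of a gene brought 10 of the 24 closer to 0 by over 1.5 times. The averaged differences were -1.20 log2 units for Gpt2, -0.86 for Slco2b1, -0.27 for Pvt1, -0.31 for Nr2c1, -0.53 for Trim26, -0.64 for Glis2, -0.81 for Csrnp1, -1.13 for Farp1, 0.84 for Amdhd1 and 1.91 for Plcxd2.

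Notch target genes did not pass as a set. Of 15 Notch target genes measured, 7 lay below the range of the negative arrays, 7 within it and 1 above it, with a median difference of -0.18 log2 units, and 0 passed limma's test over all genes or adjusted over the list alone. Notch1, a receptor and itself a target, was at 10.50 against 11.75, 11.74 and 10.85 in negative replicates 1, 2 and 3. Gata3, a T cell transcription factor, was at 5.83 against 8.22, 7.85 and 6.21. Dtx1, a regulator of Notch signalling, was at 4.17 against 8.25, 5.94 and 4.21. In its second probe set, at 4.14 against 5.23, 6.43 and 5.84, negative replicate 3 lay between replicates 1 and 2. The camera adjusted p of the list was 0.244, with 3 of its genes also held by other lists. The list passed camera, as lower in the array labelled positive, when probe sets were averaged (adjusted p = 0.0120) and without negative replicate 3 (0.00233). Neither call held with an estimated correlation, with an adjusted p = 0.866 with an estimated correlation for averaged probe sets and an adjusted p = 0.563 with an estimated correlation without replicate 3. The estimated correlation left 2 residual degrees of freedom with averaged probe sets and 1 without replicate 3. Hardly any list can pass so, and these losses alone do not show that the calls were false. Of 24 receptors, ligands and processing enzymes of the pathway, 5 lay below, 4 above and 15 within the negative range. Their median difference was -0.11, with a camera adjusted p of 0.502. Among them Jag2, a ligand, differed by -0.37 log2 units, or by -0.55 when its probe sets were averaged, and Ncstn, a subunit of gamma-secretase, by 0.35, or by -0.09 when its probe sets were averaged.

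Of the 24 gene lists tested, 4 lay lower as sets in the array labelled positive under limma's camera with a preset correlation of 0.01, and 0 lay higher. These were the macrophage, lymphoid priming, B lineage and endothelial lists. None of these calls held with a correlation estimated from the residuals, where 0 lists passed and each of the 4 had an adjusted p = 0.783 with an estimated correlation. fry passed 0 lists. With an estimated correlation camera had only the 2 residual degrees of freedom, and fry rests on the same 2. A call lost in camera with the estimate therefore does not show that correlation between genes made it. Nor do the lists that failed fry count as evidence against the calls. The estimated correlation between genes was 0.936 in the macrophage list, 0.947 in the lymphoid priming list, 0.940 in the B lineage list and 0.0954 in the endothelial list. Without negative replicate 3 it was 0.162, 0.314, -0.0667 and -0.0588 in the same order. The high values thus reflect mainly the distance of replicate 3 from replicates 1 and 2. The B lineage list, then below the preset 0.01, still did not pass with the estimate. Without negative replicate 3, 10 lists passed camera, and 3 passed without replicate 1 or without replicate 2. With an estimated correlation 0 lists passed in these refits, where the lowest adjusted p was 0.920 without replicate 1, 0.851 without replicate 2 and 0.563 without replicate 3. Among random lists matched on mean level, 6 lists had a median under the 1st percentile and 3 above the 99th. The random lists were drawn gene by gene and do not hold the correlation within a list. These ranks are therefore a description and not a test. Other lists hold 1 of the macrophage genes, 1 of the lymphoid priming genes, 0 of the B lineage genes and 2 of the endothelial genes.

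Macrophage genes had a median difference of -1.65 log2 units over 15 genes, 8 of them below the negative range and 0 above it, with a camera adjusted p of 1.08e-05 (adjusted p = 0.783 with an estimated correlation). C1qc, a chain of complement C1q, was at 8.18 in the array labelled positive, 11.94 and 11.99 in negative replicates 1 and 2, and 8.80 in negative replicate 3. Vcam1, an adhesion molecule of liver macrophages and endothelium, was at 7.31 against 11.36, 10.98 and 8.81. The difference in Vcam1 was -3.08, or -1.96 when its probe sets were averaged, and in 1 of its probe sets the array labelled positive, at 7.79, lay above negative replicate 3, at 6.66. Cd163, a haemoglobin scavenger receptor, was at 3.78 against 6.60, 7.26 and 6.20. The median difference of the list was -2.51 against replicate 1, -2.59 against replicate 2 and -0.18 against replicate 3, and -2.57 against the mean of the others without replicate 3. Over all genes, and adjusted over the list alone, 0 genes passed.

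B lineage genes had a median difference of -1.75 log2 units over 10 genes, 7 below the negative range and 0 above it, with a camera adjusted p of 0.000894 (adjusted p = 0.783 with an estimated correlation). Cd79a, a signalling chain of the B cell receptor, was at 7.44 against 11.72, 12.19 and 8.28 in negative replicates 1, 2 and 3. Ebf1, a transcription factor of early B cells, was at 5.90 against 10.13, 9.97 and 6.61, and Blnk, an adaptor of B cell receptor signalling, at 5.84 against 8.90, 8.55 and 6.75. Lymphoid priming genes had a median of -0.60 over 15 genes, 7 below the range and 0 above it, with a camera adjusted p of 0.000261 (adjusted p = 0.783 with an estimated correlation). Il7r, the interleukin 7 receptor, was at 8.39 against 12.11, 11.75 and 8.89. Flt3, a cytokine receptor of multipotent and lymphoid progenitors, was at 11.07 against 12.12, 11.95 and 11.63, and Bcl11a, a transcription factor needed for lymphoid development, at 11.55 against 12.31, 12.38 and 11.74. The medians against replicate 3 alone were -0.30 for the B lineage list and 0.03 for the lymphoid priming list, and the lymphoid priming median was -0.36 without replicate 1. Of the other probe sets of Ebf1, 1 differed by 0.28 log2 units and the rest were lower, and the average over its probe sets was -1.89. In both lists 0 genes passed over all genes or adjusted over the list alone.

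Endothelial genes had a median difference of -0.52 over 17 genes, 9 below the negative range and 2 above it, with a camera adjusted p of 0.0316 (adjusted p = 0.783 with an estimated correlation). Cdh5, the cadherin of endothelial junctions, was at 4.83 against 9.71, 9.45 and 6.16, and Esam, an endothelial adhesion molecule also used to mark stem cells, at 6.46 against 7.86, 7.39 and 7.63. Tek, the angiopoietin receptor, was at 7.36 against 6.19, 6.04 and 6.72. The median was -0.27, -0.93 and -0.17 against negative replicates 1, 2 and 3. The call was lost without negative replicate 1, at a median of -0.65 (adjusted p = 0.0863), and without negative replicate 2, at a median of -0.43 (adjusted p = 0.304). Over all genes, and adjusted over the list alone, 0 genes passed.

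**Figure D2:**
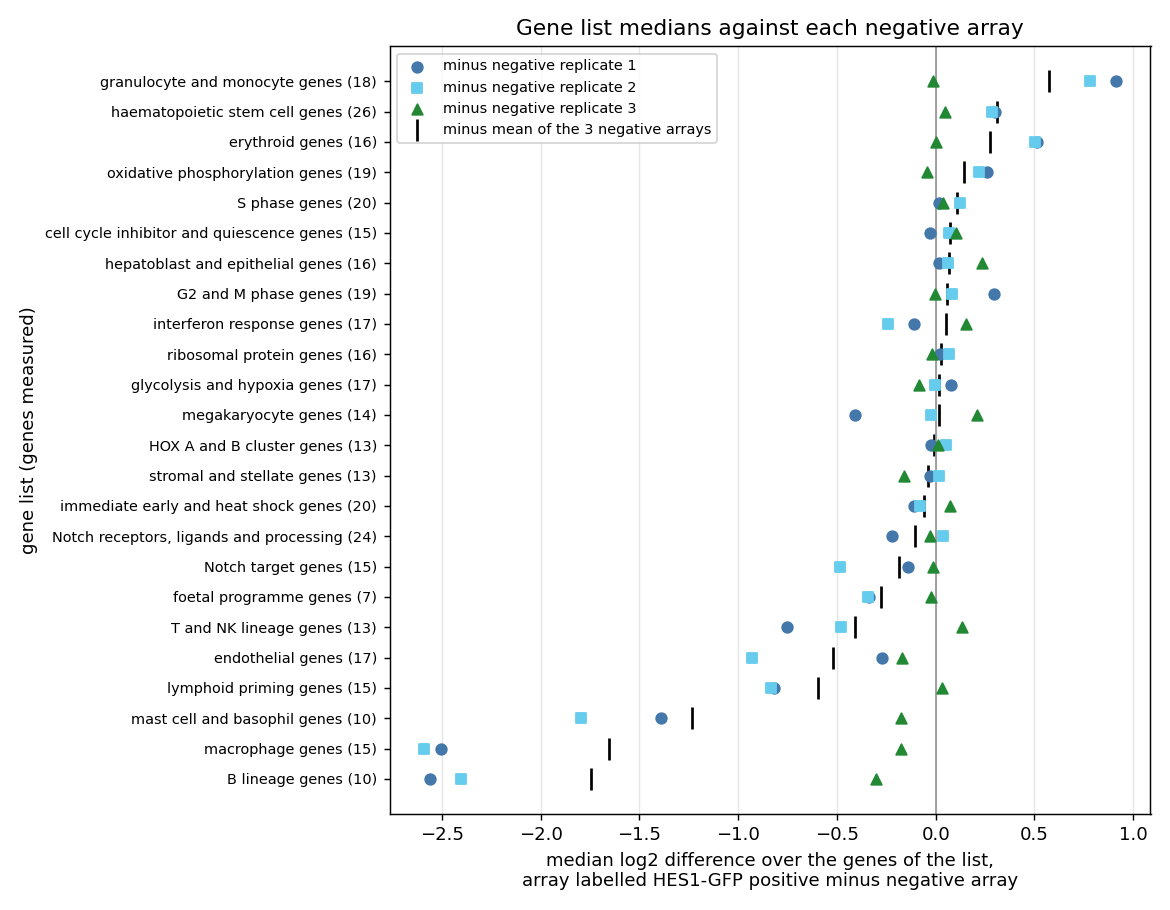
Median log2 difference over the measured genes of each of the 24 gene lists (x axis; lists on the y axis, number of genes measured in brackets) between the array labelled HES1-GFP positive and each negative array, 1 marker per negative array, with the difference from the mean of the 3 negative arrays as a black tick. For the macrophage list the markers stand at -2.51, -2.59 and -0.18 for negative replicates 1, 2 and 3.

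Lists of other blood lineages did not pass camera on the values as deposited. Granulocyte and monocyte genes had a median difference of 0.58 over 18 genes, 9 above the negative range and 3 below it, with an adjusted p of 0.0961. The median was 0.38 without replicate 1 and -0.01 against replicate 3 alone. Elane, neutrophil elastase, was at 11.65 against 8.26, 8.66 and 11.51 in negative replicates 1, 2 and 3, and Ctsg, cathepsin G, at 12.12 against 8.82, 8.37 and 12.05, while Csf1r, the receptor of macrophage colony-stimulating factor, was at 11.63 against 12.88, 12.97 and 12.13. Erythroid genes had a median of 0.27 over 16 genes (adjusted p = 0.143), which was 0.48 without replicate 3 and 0.003 against replicate 3 alone. Hbb-y, an embryonic beta-like globin, was at 10.17 against 8.32, 6.65 and 9.41, and its probe set may share signal with related globin genes. Mast cell and basophil genes had a median of -1.23 over 10 genes (adjusted p = 0.0650), which was -0.17 against replicate 3 alone. Cma1, mast cell chymase, was at 5.97 against 12.35, 12.39 and 6.22. T and NK lineage genes had a median of -0.41 over 13 genes (adjusted p = 0.158), which was -0.24 without replicate 1 and 0.13 against replicate 3 alone. In this list Thy1, a T cell surface glycoprotein, was at 6.06 against 9.13, 9.44 and 6.79, and Il2rb, a subunit of the interleukin 2 receptor, at 4.95 against 6.49, 6.35 and 5.39. Megakaryocyte genes had a median of 0.02 over 14 genes and a mean of -0.17 (adjusted p = 0.683), and the median was 0.17 without replicate 1, 0.08 without replicate 2 and -0.22 without replicate 3. Itgb3, a platelet integrin, was at 7.83 against 8.83, 8.65 and 8.98 (a difference of -0.99, or -0.64 with averaged probe sets), and Vwf, von Willebrand factor, at 5.21 against 7.98, 7.05 and 6.14. Without negative replicate 3 the granulocyte and monocyte, erythroid, mast cell, T and NK, Notch target and oxidative phosphorylation lists also passed camera, for a total of 10 lists. None of the 10 passed there with an estimated correlation, each with an adjusted p = 0.563 with an estimated correlation from 1 residual degree of freedom. With all negative arrays, the erythroid list passed when probe sets were averaged (adjusted p = 0.0472, and adjusted p = 0.866 with an estimated correlation). The mast cell and basophil list passed with only probe sets above the median level (median -2.07, adjusted p = 0.0411, and adjusted p = 0.885 with an estimated correlation).

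Haematopoietic stem cell genes had a median difference of 0.31 log2 units over 26 genes, 8 above the negative range and 3 below it, and did not pass camera (adjusted p = 0.238). The median was 0.07 with averaged probe sets and 0.05 against negative replicate 3 alone. Gfi1, a repressor that restrains stem cell proliferation, was at 10.73 against 10.30, 10.28 and 10.29 in negative replicates 1, 2 and 3, and Hoxa9, a homeobox gene of stem and progenitor cells, at 10.65 against 10.06, 10.23 and 10.33. The other probe set of Hoxa9 differed by -0.18 log2 units, and the average of its probe sets by 0.13. Foetal programme genes had a median of -0.28 over 7 genes (adjusted p = 0.502). Within that list Arid3a, a DNA-binding protein, was at 9.04 against 7.80 ± 0.15 (SD, n = 3). It was the 1 gene of any list to pass adjusted over the list alone (limma adjusted p = 0.0379), though not over all genes (0.980). That adjustment covers the 7 genes of this list and not the 24 lists, so such a pass can come by chance. Igf2bp3, an RNA-binding protein of foetal tissues, was at 11.07 against 11.29, 11.56 and 11.19. HOX A and B cluster genes had a median of -0.01 and a mean of 0.14 over 13 genes (adjusted p = 0.551), with Hoxa2 at 5.52 against 4.41, 4.22 and 4.40 and Hoxb3 at 7.05 against 5.47, 5.93 and 5.90, a difference of 1.29, or 0.80 with averaged probe sets.

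Cell cycle and housekeeping lists did not pass camera with all negative arrays. The median difference was 0.06 for G2 and M phase genes, 0.11 for S phase genes and 0.07 for cell cycle inhibitor and quiescence genes, with camera adjusted p of 0.411, 0.525 and 0.720. It was 0.14 for oxidative phosphorylation genes (0.228), 0.02 for glycolysis and hypoxia genes (0.683) and 0.03 for ribosomal protein genes (0.662). Immediate early and heat shock genes, which respond to cell handling, had a median of -0.06 (0.683), and interferon response genes 0.05 (0.864). Hepatoblast and epithelial genes, which mark the surrounding liver, had a median of 0.07 (0.676), which was 0.33 with only probe sets above the median level, -0.01 with averaged probe sets and -0.06 to 0.14 with 1 negative replicate left out. Of the 16 genes, 4 lay above the negative range, 3 below it and 9 within it. The members with the largest moderated t were the 4 above the range, none of which passed, with differences of 1.10 log2 units for Hnf4a, a hepatocyte transcription factor, 0.92 for Apoa2, an apolipoprotein, 1.55 for Fga, a chain of fibrinogen, and 1.10 for Krt18, an epithelial keratin. Stromal and stellate genes had a median of -0.04 (0.244). The median and the mean differed in sign in 5 lists (megakaryocyte, immediate early and heat shock, interferon response, glycolysis and hypoxia, HOX), and the median and camera's direction in these except the immediate early list. With 1 negative replicate left out, the medians ranged from 0.01 to 0.17 for G2 and M phase, 0.02 to 0.10 for S phase, 0.06 to 0.26 for oxidative phosphorylation, -0.11 to -0.02 for stromal, -0.34 to -0.17 for foetal programme, -0.21 to -0.10 for Notch target and -0.15 to -0.05 for Notch receptor genes. They ranged from -0.02 to 0.04 for glycolysis and hypoxia, 0.02 to 0.05 for ribosomal protein and -0.07 to 0.02 for HOX genes. Of the other genes given by value, 6 (Dtx1, Il2rb, Cd163, Hoxa2, Hoxb3 and Fga) also had no probe set with a mean above the median level of all probe sets.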

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

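The comparison with negative replicate 3 alone and the estimated correlation within refits were chosen after seeing the data, and the other alternatives before. The counts of 0 genes higher and 0 lower held under cyclic loess, the filter on dim probe sets, trend and robust eBayes (lowest adjusted p = 0.166), averaged probe sets, treat, the fit of all 45037 probe sets and without each negative replicate. Hes1 stayed lower in the array labelled positive and never passed, from -1.17 to -2.36 log2 units with 1 negative replicate left out. The 256 genes at least 1 log2 unit outside the negative range became 156 with the filter on dim probe sets, 168 with averaged probe sets, 417 to 916 with 1 negative replicate left out, and 1170 against negative replicate 3 alone; a range of fewer arrays is narrower by construction, but leaving out negative replicate 3 gave the 916, against 419 without replicate 1 and 417 without replicate 2. The 4 lists that passed camera became 0 with an estimated correlation, 0 with it under the filter, with averaged probe sets or without each replicate, 0 with fry, and 3 to 10 with 1 negative replicate left out, the 10 being without replicate 3. The macrophage, lymphoid priming and B lineage lists passed with the preset correlation under cyclic loess, the filter, averaged probe sets and without each replicate (trend and robust settings do not enter camera), and the endothelial list failed without replicate 1 (median -0.65) or 2 (-0.43), against -0.52. The Notch target list passed with averaged probe sets, at a median of -0.33 (adjusted p = 0.0120), as did the erythroid list (0.0472), and the mast cell list passed with the filter, at a median of -2.07 (0.0411); the cause was not tested. Some directions that did not pass turned with averaged probe sets: foetal programme (median -0.24), immediate early and heat shock (-0.0016), glycolysis and hypoxia (0.10) by their camera direction, and Ncstn (-0.088). With 1 negative replicate left out, the direction of camera turned in at least 1 refit for immediate early and heat shock (medians -0.073 to -0.0025), interferon response (-0.090 to 0.16) and cell cycle inhibitor genes (-0.045 to 0.066). The other 66 named genes kept their direction and stayed short of the threshold wherever the filter left them a probe set. No paired analysis was possible because the 2 groups share only replicate number 1. No detection calls were used, and the filter left 9 of the 12 named higher genes and 1 of the 12 lower ones without a probe set, and 6 others (Dtx1, Il2rb, Cd163, Hoxa2, Hoxb3 and Fga).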

Other observations

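The tests below were chosen only after the results were seen, except that on genes of the level of Hes1, and the genes named next were chosen after their values were seen. None of these genes passed the test between the labelled groups. Prg2, eosinophil major basic protein, had log2 intensities of 6.85 and 5.96 in HES1-GFP negative replicates 1 and 2, 12.34 in negative replicate 3 and 12.25 in the array labelled positive. Epx, eosinophil peroxidase, was at 4.24, 4.77, 8.56 and 7.90 in the same order, and Prg3, a homologue of Prg2, at 4.99, 4.91, 8.50 and 8.62. Rag1, the recombinase of lymphocyte receptor genes, was at 11.85, 11.54, 7.20 and 7.32, Ly6d, a marker of early lymphoid commitment, at 11.81, 11.63, 7.63 and 7.66, and Msr1, a macrophage scavenger receptor, at 9.69, 9.65, 5.31 and 4.94. Igf2, a foetal growth factor, was at 11.14, 11.04, 7.90 and 9.36.

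Hes1 was low in the array labelled HES1-GFP positive and in negative replicate 3, and high in the other 2 negative arrays. A single exchange of the positive label with 1 negative label would leave 1 array alone with high Hes1, but the second highest array lay 2.09 log2 units above the third, against gaps of 0.29 above and 0.13 below, so 1 exchange does not account for the values if Hes1 transcript follows the reporter. The authors' normalization would lower genes of the same level alike. The 2064 genes within 0.5 log2 units of Hes1 differed by a median of 0.0924 from negative replicate 1 and 0.0939 from replicate 2. Equalizing the distributions of the arrays makes such medians small by construction, so they cannot count against the normalization. They show only that Hes1 moved relative to genes of its level. An unrecorded processing batch cannot be told apart from the other explanations, since the 3' minus 5' signal of the Gapdh and Actb control probe sets splits the arrays as Hes1 does, but only over ranges of 0.13 and 0.06 log2 units, and the labels give no batch. Other wrong labels, a Hes1 transcript that does not follow GFP, and a difference between sorts in what the gate held stay open and may act together.

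The macrophage, lymphoid priming and B lineage lists were lower in the array labelled positive with a preset correlation, and none passed with an estimated correlation (adjusted p = 0.783). The gate as labelled would put negative replicate 3 with the other negative arrays, but the medians of the array labelled positive against replicate 3 were -0.18, 0.03 and -0.30, each closer to 0 than those against replicates 1 and 2, which argues against it as the cause for these 3 lists but leaves it open for the endothelial list, at -0.17 against replicate 3, -0.27 against replicate 1 and -0.93 against replicate 2. More cells of every other type in negative replicates 1 and 2 would raise all lineage lists there, but the granulocyte and monocyte list was higher in the array labelled positive by a median of 0.91 against replicate 1 and 0.78 against replicate 2, although early progenitors also express some of these genes. Each of the 4 arrays taken alone against the other 3 passed at least 4 lists, the real value being 4 and the highest of the others 7 (0 in each with an estimated correlation), with these 3 lists higher for replicates 1 and 2 and lower for replicate 3 and the array labelled positive, and for the genes at least 1 log2 unit outside the range the real value was 256 and the highest other 431, as large in all 4 arrays, with 4 splits too few for a share under 0.05. A difference in cell composition between the samples, limited to some lineages, is a candidate explanation that stays open. The sort for lineage-negative cells is meant to remove mature cells, but how completely it did so was not measured. A difference by GFP also stays open if more than 1 label is wrong.

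All 4 samples are labelled female. The probe sets used for Xist, the X-inactivating RNA, had log2 intensities of 10.84 to 11.13 over the 4 arrays, and those for the Y-linked genes Kdm5d, Eif2s3y and Uty of 8.79 to 9.51, 8.21 to 9.39 and 5.91 to 6.96. Among all genes of an array, Kdm5d lay at percentiles 68.3 to 77.0, Eif2s3y at 61.1 to 75.6 and Uty at 35.3 to 47.5. The signal of Kdm5d and Eif2s3y, above that of most genes in every array, goes against a label of female cells alone. Without detection calls, and with Uty lower, these values do not settle whether a Y-linked transcript was present.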
